A study of Mus musculus with 6 samples.

How the data were processed

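Gene expression was measured in mouse B-cell acute lymphoblastic leukaemia (B-ALL) cells that carry the BCR-ABL oncogene. Per the labels' protocols, the cells were treated for 4 h with 312 nM dihydroartemisinin (DHA, the active form of the artemisinin antimalarial drugs) or with the vehicle dimethyl sulphoxide (DMSO), and biotin-labelled cRNA made from total RNA was hybridised to Affymetrix arrays. The agent named for each sample put 3 samples in the vehicle group and 3 in the DHA group. Replicate numbers were given in accession order and only name the samples. The extraction protocol also mentions 2 h, whereas the treatment protocol names 4 h alone, so 4 h was used. The growth protocol covers lines with or without the T315I mutation and lacking Arf or p53, and which of them was on these arrays is not given in the sources used here. The labels do not say that the samples came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

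The deposited values were log2 intensities, 1 per probe set and sample. They were summarised with RMA (robust multi-array average) and Partek version 6.6 was used, per the submitters' processing notes. Settings and order of these steps are not given in the sources used here. RMA as usually run subtracts background and equalises the distributions of probe intensities before they are summarised into probe sets. The 6 distributions of summarised values here were close and not identical, which does not tell whether any of its steps was left out. Fold changes of dim genes on such arrays tend to be understated. No missing values occurred among the 41345 probe sets. Array medians lay between 5.25 and 5.31, minima between 2.08 and 2.20 and maxima between 13.52 and 13.56. No scanner file was used here, so scan date and spot quality were not analysed here. With 3 arrays per group, the number of arrays limits the precision.

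Probe sets were named through the platform annotation, with symbols updated through the Entrez identifier to RefSeq (assembly GRCm38.p6). The annotation gave 1 gene symbol for 23521 probe sets, several for 1814 and did not name 16010. Of the single-gene probe sets, 23328 matched RefSeq and the others kept the symbol of the annotation. Probe sets with several genes or unnamed here entered no gene-level comparison and were tested only in the alternative that tests each probe set. The genome build behind the annotation is not given in the sources used here, so no coordinates are printed. For each of 22180 genes, the probe set with the highest mean over the 6 arrays was used, and 1082 genes had more than 1. Genes with a mean under the 30th percentile (4.52 on the log2 scale) were left out, which removed 6654 and left 15526.

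DHA was compared with vehicle with limma version 3.58.1 in R version 4.3.3 (linear model, empirical Bayes moderation with default settings, two-sided). The residual degrees of freedom were 4 and the prior degrees of freedom 2.77. Genes at a Benjamini-Hochberg adjusted p at or under 0.05 were called changed. For Mcl1, an exact two-sided permutation test of the 3 against 3 values was run on each probe set, and its smallest possible p is 0.1. Gene groups were tested with limma's camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over 29 lists with at least 5 tested members). The lists held 664 distinct genes, of which 561 were tested, and 4 were matched through a synonym. Among these, Gpi1 of the hypoxia and glycolysis list was matched to Pigq, a different gene, which was counted in its place. Members past the test were counted over all genes and adjusted over the list alone. Intervals are 95% confidence intervals from limma, unadjusted for the number of genes.

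The comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Mcl1 and each tested member of the BCL-2 family, up to 12 called genes in each direction with the largest changes, separate groups and a descriptive name, up to 4 members of each list with the smallest p, and any called marker of another cell type. Genes outside the rule are said to have been chosen after their values were seen. Alternatives were leaving out each array, no filter or a filter at the 50th percentile, median centring or quantile normalization, other ways of joining the probe sets of a gene, testing each probe set, other variance settings, array weights, other thresholds, and other set tests. A term for a title code shared by 1 vehicle and 1 DHA sample, and leaving out both, were added after seeing the data.

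The procedure was tested on simulated data for the comparison of DHA with vehicle, with 15526 genes of which 200 were changed, in 20 simulations. It recovered 88.4% of genes changed by 0.5 on the log2 scale, 99.5% of those changed by 1 and 100% of those changed by 2, and 5.19% of calls were false. Noise was drawn independently for each gene from limma's moderated standard deviations, so these shares may not hold on the real arrays. There, Trib3 rose by 1.65 and was not called (limma adjusted p = 0.0636). With no effect and independent genes, 0.05 lists were called on average. A list shifted by 0.3 was called in 20 of 20 simulations.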

Results

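The series profiled gene expression in mouse BCR-ABL-positive B-ALL cells after 4 h with 312 nM DHA or vehicle, with 3 arrays per group. Its title concerns sensitivity to navitoclax, an inhibitor of BCL-2 family proteins, and repression of MCL-1, an anti-apoptotic member of that family. Pearson correlations between arrays ranged from 0.9925 to 0.9947, and no pair held identical values. The leading principal component carried 36.7% of the variance and separated the groups. Vehicle replicate 1 (-7.17) and DHA replicate 2 (4.41) were the nearest pair across the groups on it. Vehicle replicate 3 and DHA replicate 2, which share an unexplained title code, were the most alike pair of all (0.9947). The median log2 fold change of the 15526 tested genes was 0.0027, with a median standard error (SE) of 0.068.

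The 2 largest rises after DHA, Ddit3 and Chac1, were in genes of the integrated stress response, the programme that follows phosphorylation of eIF2α and is carried by the transcription factors ATF4 and CHOP. Ddit3, which encodes CHOP, rose 5.58-fold, from 7.48 ± 0.13 to 9.96 ± 0.35 on the log2 scale (SD, n = 3 per group; limma adjusted p = 0.0225). Chac1, a glutathione-degrading enzyme, rose from 8.55 ± 0.51 to 10.76 ± 0.11 (adjusted p = 0.0461, limma). The transcription factor Atf3 rose by 1.73 (SE 0.17), the stress-induced regulator Nupr1 by 1.76 (SE 0.17) and Sesn2, an inhibitor of mTORC1 signalling, by 1.86 (SE 0.15), with adjusted p of 0.0355, 0.0355 and 0.0234. Mthfd2, an enzyme of mitochondrial folate metabolism, rose by 0.67 (SE 0.067; adjusted p = 0.0379).

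Outside that list, Egr1, an immediate early transcription factor, rose by 1.90 (SE 0.14; adjusted p = 0.0225), and Cd69, a lymphocyte activation marker, rose from 9.26 to 10.81 (SE of the difference 0.15; adjusted p = 0.0355). The neutral amino acid transporter Slc1a4 rose by 1.23 (SE 0.10; adjusted p = 0.0234). Smaller rises were in Arl14ep (0.93, SE 0.083), Arl11 (0.81, SE 0.087), the small nucleolar RNA host gene Snhg1 (0.55, SE 0.042) and the organic anion transporter Slco4a1 (0.45, SE 0.044), with adjusted p of 0.0340, 0.0461, 0.0225 and 0.0355. Klhl21, a substrate adaptor of a ubiquitin ligase, fell from 6.90 to 6.40 (log2 fold change -0.50, SE 0.053; adjusted p = 0.0461). Trib3 (1.65, adjusted p = 0.0636) and Atf4 (0.50, adjusted p = 0.0660) missed the threshold. Trib3, Atf4 and Slco4a1, the smallest called rise, lay outside the naming rule and were chosen after their values were seen.

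In all, limma called 14 genes, 13 up and 1 down, with separate groups in each of the 14. At 2-fold or more there were 8. Groups were separate in 15.83% of tested genes against 10% by chance. At an unadjusted p under 0.05 there were 923 genes up and 944 down, where 776.3 in all would arise by chance. Without vehicle replicate 1, 2 or 3 or DHA replicate 1 or 3, limma called 0 genes in each case, with 1581, 1710, 1660, 1356 and 1545 genes at an unadjusted p under 0.05, and without DHA replicate 2 it called 24, of which 11 were among the 14. The count moved to 41 up and 11 down after median centring and to 52 up and 11 down after quantile normalization. With a term for the shared title code the count moved to 37 up and 4 down, and without both samples that share the code to 0. The 14 genes kept their sign in each of 17 alternatives. As their groups were separate, leaving out arrays could not reverse a sign, so this is no further support for them.

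**Figure D1:**
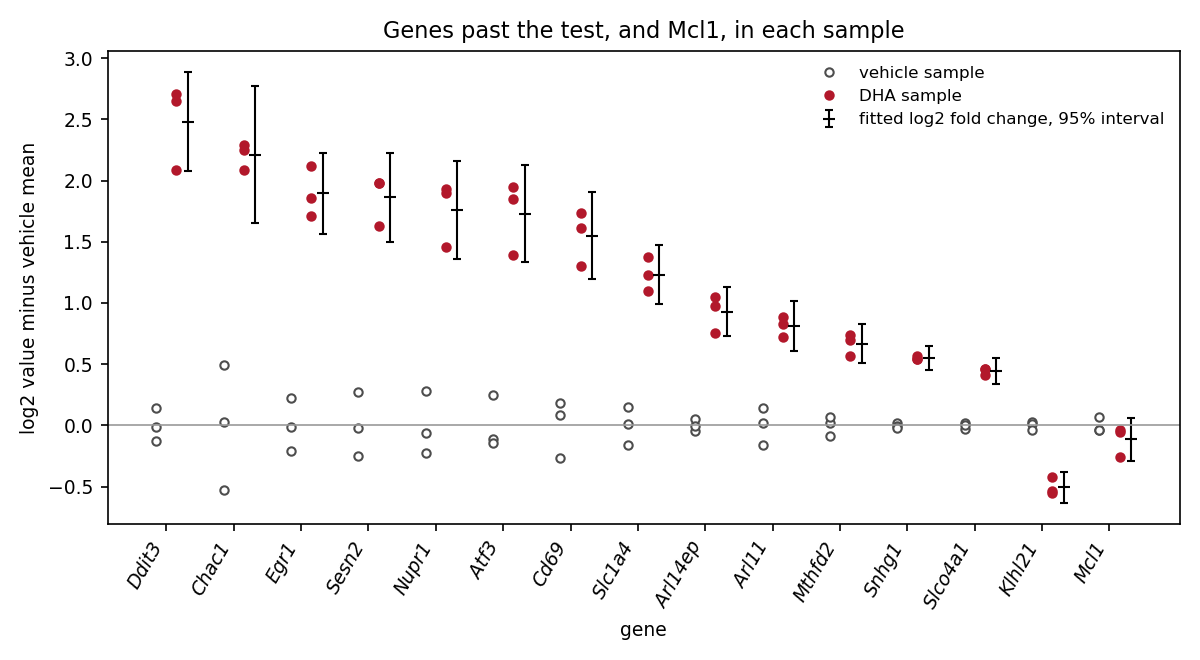
Log2 value minus the vehicle mean (vertical axis) for the 14 called genes and Mcl1 (horizontal axis), with 3 vehicle samples as open circles, 3 DHA samples as filled circles and the limma log2 fold change with its 95% interval as a bar. DHA samples lie on 1 side of the vehicle samples for each called gene, from Ddit3 (2.48) to Klhl21 (-0.50), and overlap them for Mcl1.

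Mcl1 RNA, which encodes MCL-1, was not called changed. Its brighter probe set (17400418) measured 9.71 ± 0.063 with vehicle and 9.59 ± 0.12 with DHA (SD, n = 3 per group; exact permutation p = 0.2, with 0.1 the smallest possible). The log2 fold change was -0.11 (SE 0.073, 95% interval -0.29 to 0.061; limma adjusted p = 0.582). A dimmer probe set (17407826) measured 6.94 ± 0.14 and 7.02 ± 0.32, a difference of 0.075 in the other direction (n = 3 per group; exact permutation p = 0.8). Protein was not analysed here.

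None of the other tested BCL-2 family genes passed the test over all genes. Among genes encoding anti-apoptotic members, log2 fold changes were -0.18 for Bcl2l1 (SE 0.072; adjusted p = 0.395), 0.12 for Bcl2l2, 0.027 for Bcl2a1a and -0.011 for Bcl2, and 0 of 5 passed when adjusted over the list alone. Among 10 pro-apoptotic genes, 1 rose and 2 fell when adjusted over the list alone. Bok, an effector related to Bax and Bak, had a log2 fold change of -0.37 (limma adjusted p = 0.00953 adjusted over the list alone and 0.124 over all genes). Bnip3 had -0.47 and Pmaip1, which encodes the MCL-1-binding protein NOXA, 0.21 (limma adjusted p = 0.0421 for both, adjusted over the list alone). Bak1 (-0.19), Bid (-0.10), Bik (0.10), Bcl2l11 (0.035), Bmf (0.023), Bbc3 (0.0091) and Bad (-0.00070) did not pass. By camera, the anti-apoptotic list had an adjusted p of 0.604 (median -0.011) and the pro-apoptotic list 0.363 (median 0.0042). Bax, Bnip3l, Bcl2a1b and Bcl2a1d were not analysed here, and Bcl2l10 and Hrk lay under the filter. Signs of Bad, Bbc3, Bcl2, Bcl2a1a, Bcl2l11 and Bmf changed on leaving out an array, and that of Bad also under quantile normalization.

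**Figure D2:**
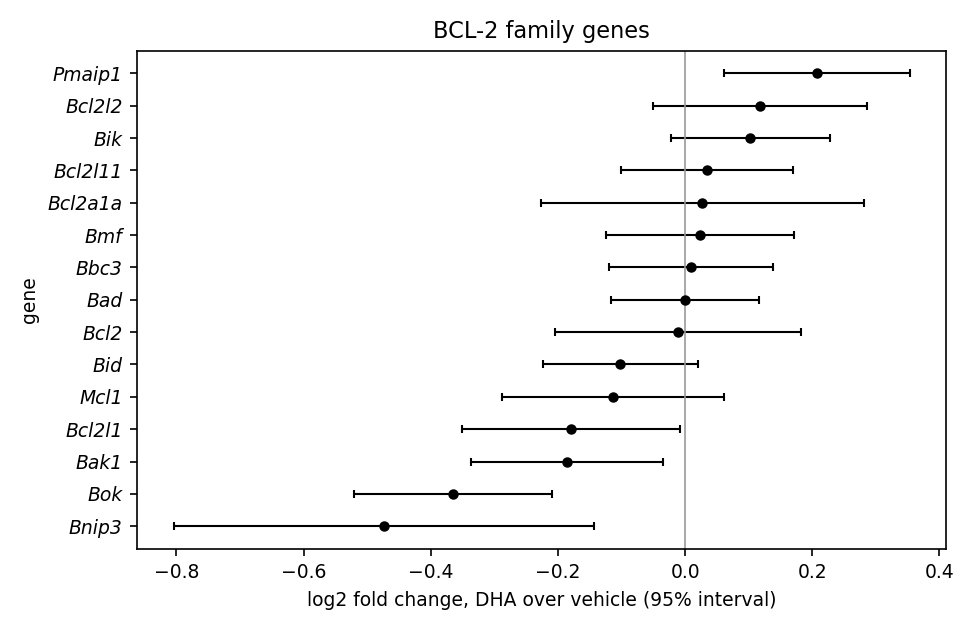
Log2 fold change of DHA over vehicle (horizontal axis) for the tested BCL-2 family genes, with unadjusted 95% intervals from limma as bars. Values run from -0.47 for Bnip3 to 0.21 for Pmaip1, with Mcl1 at -0.11 and an interval that spans 0.

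The integrated stress response list lay higher after DHA as a group. Of its 32 tested genes, 32 were higher, 6 rose over all genes and 26 rose when adjusted over the list alone. The median log2 fold change was 0.49 (camera adjusted p = 4.86e-32). The adjusted p was 0.434 with an estimated correlation. The mean level of the list was 8.40 ± 0.10 with vehicle and 9.15 ± 0.15 with DHA (SD, n = 3 per group; exact permutation p = 0.1, the smallest possible). Per DHA array it was 9.26, 8.97 and 9.21.

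Aminoacyl-tRNA synthetase genes of the cytosol, which charge tRNAs with amino acids, had a median log2 fold change of 0.19 (camera adjusted p = 7.65e-06, and adjusted p = 0.447 with an estimated correlation). Of 18 tested, 8 rose and 0 fell when adjusted over the list alone, among them Cars (0.64), Sars (0.39), Gars (0.33) and Lars (0.31). Genes of cholesterol synthesis had a median of 0.11 (camera adjusted p = 0.00230, and adjusted p = 0.447 with an estimated correlation), and 2 of 19 rose when adjusted over the list alone, Msmo1 (0.37) and Fdft1 (0.27). NF-kB and inflammatory genes had a median of 0.13 (camera adjusted p = 0.0312, and adjusted p = 0.447 with an estimated correlation). Of these 16, 2 rose and 1 fell when adjusted over the list alone. Rel, an NF-kB subunit, had 0.43, Nfkbiz 0.27 and the cytokine Tnf -0.40. Without vehicle replicate 2 or DHA replicate 1 the NF-kB list lost its call (medians 0.11 and 0.066, adjusted p = 0.131 and 0.164), and with no filter its median was 0.084. Without vehicle replicate 3 the cholesterol median was 0.047 (adjusted p = 0.0226).

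Genes of the G2/M phases of the cell cycle lay lower after DHA, with a median log2 fold change of -0.099 and 27 of 32 lower (camera adjusted p = 1.31e-08, and adjusted p = 0.434 with an estimated correlation). When adjusted over the list alone, 8 fell and 0 rose. These included the kinesin Kif2c (-0.26), the spindle midzone protein Prc1 (-0.46), the mitotic kinase Plk1 (-0.25) and Hmmr (-0.24), each at a limma adjusted p = 0.0151, adjusted over the list alone. The G1/S and DNA replication list had a median of 0.033 (camera adjusted p = 0.2998), with 2 of 28 up adjusted over the list alone, the replication licensing factor Cdt1 (0.39) and Tyms (0.24).

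Genes of endoplasmic reticulum (ER) chaperones and ER-associated degradation had a median log2 fold change of -0.15 (camera adjusted p = 2.72e-05, and adjusted p = 0.447 with an estimated correlation). Of 23 tested, 10 fell and 1 rose when adjusted over the list alone. The chaperone Hspa5 had -0.41, the disulphide isomerase Pdia6 -0.32 and Creld2 -0.23, while Herpud1, a component of ER-associated degradation, had 0.66. Hypoxia and glycolysis genes had a median of -0.15 (camera adjusted p = 3.34e-05, and adjusted p = 0.447 with an estimated correlation), with 8 down and 1 up of 25 adjusted over the list alone. These 25 include Pigq (-0.049), matched in place of the glycolytic gene Gpi1, and the list was not tested without it. The glycolytic enzymes Tpi1 and Pfkl had -0.43 and -0.62 and the oxygen sensor Egln1 -0.31, while the growth factor gene Vegfa had 0.56. Heat shock genes had a median of -0.10 (camera adjusted p = 0.00391, and adjusted p = 0.447 with an estimated correlation) with 0 of 15 past the test adjusted over the list alone, where Hsph1 had the smallest p (-0.34). Most of these 15 are cytosolic, but Hspd1 and Hspe1 also stand in the list of mitochondrial proteases and chaperones. Respiratory chain subunits had a median of -0.045 (camera adjusted p = 0.00438, and adjusted p = 0.447 with an estimated correlation) with 0 of 29 past the test adjusted over the list alone. Without vehicle replicate 1 the hypoxia and glycolysis median was -0.070 (adjusted p = 0.00356). Without vehicle replicate 2 the heat shock and respiratory chain lists lost their calls (medians -0.046 and -0.026, adjusted p = 0.131 for both), as did the latter without DHA replicate 3 (median -0.040, adjusted p = 0.0605), and its median was -0.068 without vehicle replicate 3 and -0.077 without both samples of the shared title code.

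Camera called 9 of the 29 lists, 4 up and 5 down, 0 held with an estimated correlation, and fry, which tests whether a list moves on balance 1 way, called 2, the integrated stress response and G2/M lists (adjusted p = 0.0312 for both). The same camera setting called each of the 9 lists in 2 to 7 of the 10 splits of the samples into 3 and 3, the real split included. Of the lists not called, immediate early and AP-1 genes had a median log2 fold change of 0.052 (camera adjusted p = 0.0561), with Egr1 and Klf6 (0.34) up adjusted over the list alone. NRF2 antioxidant targets had a median of -0.078 (adjusted p = 0.0798), although the heme-degrading enzyme Hmox1 had 0.91 (limma adjusted p = 0.0105, adjusted over the list alone). Hmox1 also rose in the heme and iron list adjusted over that list alone, where the transferrin receptor Tfrc fell (-0.39), with a list median of -0.034 (adjusted p = 0.2998). The p53 target list had a median of 0.0091 (adjusted p = 0.604), with the ribonucleotide reductase subunit Rrm2b up (0.77) and Sesn1 down (-0.32) adjusted over the list alone. Autophagy and lysosome genes had a median of -0.020 (adjusted p = 0.352), with the kinase Ulk1 down (-0.28) adjusted over the list alone.

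Camera adjusted p was 0.0561 for proteasome subunits (median -0.050), 0.262 for BCR-ABL and STAT5 targets (median -0.013), 0.352 for interferon-stimulated genes (median 0.064) and 0.392 for MYC targets (median -0.032). It was 0.604 for FOXO targets (median -0.019), 0.770 for cytosolic ribosomal protein genes (median 0.013) and 0.992 for mitochondrial proteases and chaperones (median -0.023). No member of these 7 lists passed the test adjusted over its list alone. The B-cell precursor list, which describes the leukaemia's own lineage, had a median of 0.010 (adjusted p = 0.705, 0 of 25 past the test adjusted over the list alone). Rag2, which encodes a subunit of the V(D)J recombinase, had a log2 fold change of -0.53 (SE 0.15; limma adjusted p = 0.253). Markers of other cell types passed in neither direction, with adjusted p of 0.992 for T and NK cells (median -0.022, 8 of 18 tested), 0.834 for myeloid cells (0.033, 12 of 18), 0.268 for erythroid cells and megakaryocytes (0.056, 6 of 14) and 0.341 for stromal cells (0.030, 12 of 16). No marker passed adjusted over its list alone. For pro-apoptotic, p53, FOXO, B-cell precursor, ribosomal, myeloid, T and NK cell and mitochondrial protease genes, the median, mean and camera direction differed in sign.

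**Figure D3:**
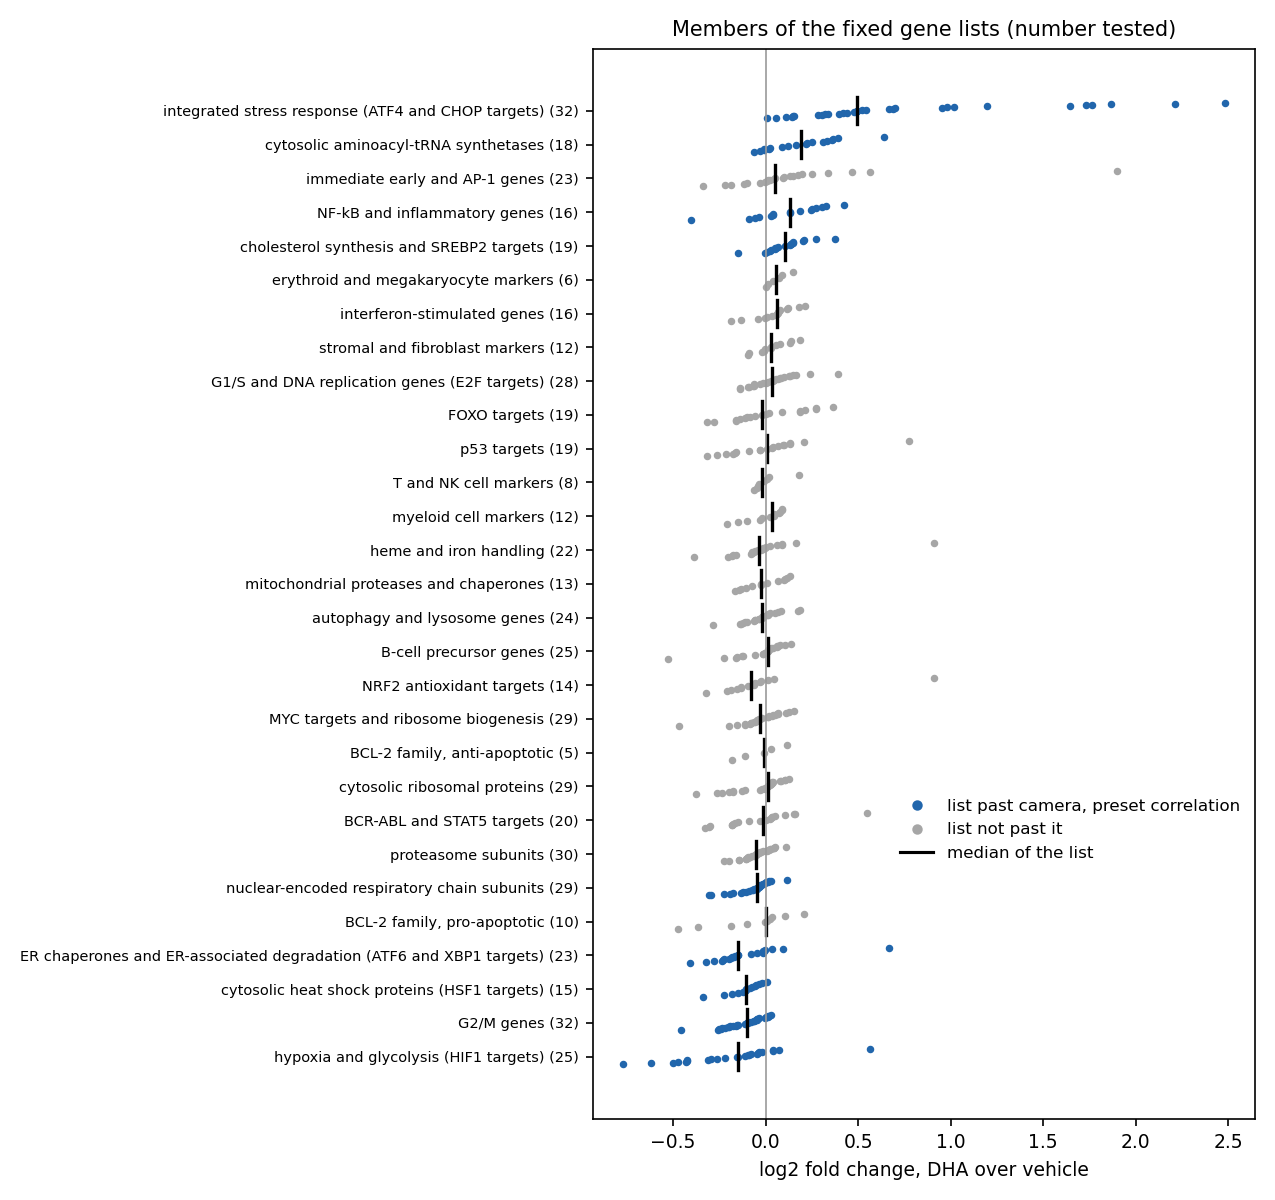
Log2 fold change of DHA over vehicle (horizontal axis) for each tested member of the 29 lists (vertical axis, number tested in brackets), with the list median as a black line and lists called by camera with a preset correlation in blue. The 32 integrated stress response genes all lie above 0 with a median of 0.49, and 27 of the 32 G2/M genes lie under 0.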

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

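Probe sets without a single gene entered no gene-level comparison. When all 28941 probe sets above the filter were tested with limma, 11355 of them without a single gene, 2 passed at an adjusted p at or under 0.05 and 1 of these was without a single gene. That probe set (17284554) was higher by 1.11 on the log2 scale with DHA (SE 0.063; adjusted p = 0.0345), at 9.33 with vehicle and 10.43 with DHA. The other was a probe set of Phf10 (17341148), higher by 1.28 (adjusted p = 0.0142), whereas the brighter Phf10 probe set used for the gene had a log2 fold change of 0.39. Further probe sets without a single gene, higher or lower, narrowly missed the threshold. Examples chosen after their values were seen are 17284533 (1.35, limma adjusted p = 0.0715) and 17202967 (-0.92, limma adjusted p = 0.0854). No explanation was tested for these values.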

How the results depend on the processing

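The title-code term and leaving out both samples with that code were chosen after seeing the data. No paired analysis was possible because vehicle and DHA shared only 1 title number, on vehicle replicate 3 and DHA replicate 2, and replicate numbers came from accession order. The count of changed genes, 14, depended strongly on the settings. It ranged from 0 to 24 on leaving out 1 array. It was 5 with no filter, 62 with the 50th percentile filter, 52 after median centring, 63 after quantile normalization, 2 with each probe set tested, 62 with trend and robust moderation and 1 without moderation. It was 0 at an adjusted p of 0.01, 80 at 0.1, 8 at 2-fold or more and 2 with treat. The title-code term gave 41 and leaving out both samples 0, with 1569 genes at an unadjusted p under 0.05. Fewer samples or tested genes are part of the construction of some of these, and otherwise the cause was not tested. Mean of probe sets (15), highest variance (16) and array weights (13) stayed within 1.5 times. The count of called lists, 9, was 0 with an estimated correlation and 2 with fry, and otherwise ranged from 6 to 11. Called lists kept their direction in each of 18 alternatives.

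The Mcl1 log2 fold change ranged from -0.15 to -0.043 on leaving out 1 array and was 0.075 with the probe set of highest variance. It passed the test in none of its alternatives. Ranges on leaving out 1 array that included a reversal were -0.029 to 0.031 for Bad, -0.029 to 0.038 for Bbc3, -0.052 to 0.071 for Bcl2, -0.095 to 0.11 for Bcl2a1a, -0.0086 to 0.064 for Bcl2l11, -0.037 to 0.057 for Bmf and -0.12 to 0.030 for Cd8b1. For list medians they were -0.021 to 0.019 for B-cell precursor, -0.044 to -0.0015 for FOXO, -0.057 to 0.012 for MYC, -0.037 to 0.0087 for T and NK cell, -0.014 to 0.038 for ribosomal, -0.043 to 0.018 for mitochondrial protease and -0.026 to 0.065 for myeloid genes, where reversal refers to camera's direction. Other reversals were Bad under quantile normalization (0.0072) and, with both title-code samples left out, Bad (0.025), Bbc3 (-0.043) and Bcl2a1a (-0.093). Camera's direction also reversed for mitochondrial proteases with no filter (-0.023), median centring (-0.026), quantile normalization (-0.013), mean of probe sets (-0.023), highest variance (-0.025), ranks (-0.023) and the title-code term (-0.023). It reversed for T and NK cell genes under quantile normalization (-0.016), highest variance (-0.022), array weights (-0.012), ranks (-0.022) and without both title-code samples (-0.028), and with the 50th percentile filter for ribosomal (0.014) and myeloid genes (-0.10). The cause was not tested.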

Other observations

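The histone and host gene sets, the tests of the integrated stress response and G2/M patterns, and the test of small nucleolar RNAs were chosen after the values were seen. Replication-dependent histone genes were mostly higher after DHA. Of 22 tested, 19 were higher with a median log2 fold change of 0.22, and 13 rose and 1 fell when adjusted over the set alone. H2aw had 1.34, H2bc14 0.79 and H1f2 0.54, while H2ac21 had -0.41. Camera was adjusted over 4 sets: these histone genes, the host genes, and the decay factors and small nucleolar RNAs used to test explanations. For the histone genes it gave an adjusted p of 2.33e-08, and an adjusted p of 0.279 with an estimated correlation. The adjustment does not cover the choice of the set after its values were seen. Neither these p-values nor the counts adjusted over the set alone can therefore test whether the set moved. Near-identical histone genes can share signal on the array.

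Host genes of small nucleolar RNAs moved unequally. Snhg1 (0.55), Zfas1 (0.77), Snhg5 (0.64) and Snhg6 (0.28) rose when adjusted over the set alone, and the other 11 of 15 did not pass. The set median was -0.0028 (-0.059 to 0.053 on leaving out 1 array), although camera's direction was up (adjusted p = 0.0390, and adjusted p = 0.279 with an estimated correlation). As the host gene set was also chosen after its values were seen, its p-values cannot test it either. A second probe set of Snhg17 had 0.83 where the brighter 1 had -0.084. Less nonsense-mediated decay and higher transcription of the host loci cannot be told apart as candidate explanations. Decay factors that are known to be autoregulated had a median of 0.079 (0.056 to 0.11 on leaving out 1 array), between the bounds set before for and against the former, and the 2 measured small nucleolar RNAs of these hosts had a median of -0.084 (-0.16 to 0.030 on leaving out 1 array), too few to decide on the latter. Camera's adjusted p was 0.280 for the decay factors and 0.454 for these RNAs.

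The integrated stress response list was higher in each DHA array than in each vehicle array. Its median log2 fold change stayed at 0.490 or above after median centring or quantile normalization. The deposited arrays were already close in their distributions, so this cannot decide on the normalization as a source. On leaving out any 1 array the median stayed at 0.447 or above. In a list picked for its difference, this shows only that no 1 array made the whole difference. The gap between the lowest DHA and the highest vehicle array was 0.469 against a larger group SD of 0.154, so no array lay with the other group in this list. The list was picked for its difference between the labelled groups, so the gap cannot decide on a mislabelled array. These tests leave activation of this response by DHA as a hypothesis, for which no test beyond the comparison of the groups was run.

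G2/M genes were lower by a mean of 0.15 relative to G1/S genes after DHA (difference -0.151, exact permutation p = 0.1 with 3 arrays per group, the smallest possible). The G1/S list itself had not fallen (median 0.033). As the G2/M list was picked for its fall and both medians were known, the difference cannot decide on a loss of cycling that lowers all cycle genes alike. The median of the G2/M list stayed at -0.0870 or further from 0 under both other normalizations. As the deposited arrays were already close in their distributions, this cannot decide on the normalization as a source. A change in the share of cells in G2/M and a change of transcription within cells stay open.

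Over the 10 splits of the 6 samples into 3 and 3, the real split was the only 1 with 14 genes, and the highest other gave 0. At an unadjusted limma p under 0.05 the real split gave 1867 genes and the others 302 to 1027. The split with 1027 had vehicle replicate 3 and DHA replicate 2 on the same side. For lists, 3 of the 10 splits gave 9 or more, and the highest other gave 9. Counting the real split, camera called the integrated stress response list in 7 of the 10 (smallest adjusted p in another split 2.33e-08) and hypoxia and glycolysis in 5. It called G2/M, aminoacyl-tRNA synthetase and heat shock genes in 4. The ER chaperone and degradation, cholesterol and respiratory chain lists were called in 3 and NF-kB genes in 2. The other splits keep part of the difference between treatments. These splits are too few for a share under 0.05. The shift of the hypoxia and glycolysis list was 0.1935 in the real split and 0.1932 in the highest other, and that of the respiratory chain list was reached by 2 of 10. Vehicle replicate 3 and DHA replicate 2, which share a title number, had a residual correlation across genes of 0.264, where the 8 other pairs between groups ranged from -0.186 to 0.0979. Genes are not independent replicates.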
